A study of Mus musculus with 14 samples.

How the data were processed

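Poly(A) RNA from cultured mouse small cell lung cancer cells was measured by RNA sequencing in 14 libraries. Per the submitters' processing notes, reads were aligned to mm10 with STAR 2.4.2 and counted over genes with featureCounts, for which no version was given. The gene annotation was not given in the sources used here. The table as deposited by the authors held raw counts in whole numbers for 32926 gene symbols and 14 libraries, and every column was used. Of the symbols 30152 (91.6%) occurred in the GENCODE M21 annotation, which served only for coordinates. A further 25 had been turned into dates, and 10220 had 0 counts in all libraries. Symbols with the prefix mt- held 2.84% to 5.18% of the counts of a library, and 13 of them were 0 in all libraries. Library totals ran from 6730816 to 10659524 counts. A group at 0 allows up to 3 counts over the whole group, 0.104 to 0.152 CPM, and a fold against such a group is given as at least its value at that floor, from the counts of the higher group pooled over its libraries. With 1 to 3 counts over the group the ratio is given with its 95% counting interval. Floors and intervals cover counting error only.

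Libraries were grouped by the labels into NE and Non-NE (n = 3 each) and YAP5SA days 0, 3, 7 and 21 (n = 2 each). Counts were scaled by TMM, genes with low counts were removed with filterByExpr, and genes were tested with the robust quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment and calls at 0.05. Non-NE and NE were compared within their 6 libraries (12966 genes), the days within their 8 libraries (13996 genes), and comparisons across both sets in a fit of all 14 (14829 genes). The biological coefficient of variation was 0.399, 0.0548 and 0.293 in these fits. The 34 gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, beside camera with an estimated correlation and fry. The 781 listed symbols, some of them synonyms, matched 778 symbols of the table, with 0 unmatched. A listed gene near 0 in one group passed the count filter only if it was higher in another. For lists with many such genes the filter therefore fixed part of the direction. State scores used the 200 genes highest in Non-NE and the 200 highest in NE among called genes, as mean log2(CPM + 1) scaled to 0 at the NE mean and 1 at the Non-NE mean.

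The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. That rule took Yap1 and the floxed genes first. For Non-NE against NE and day 21 against day 0 it took the 10 called genes with the largest rise and the 10 with the largest fall, with at least 10 CPM in the higher group, no overlap between libraries of the groups and no clone name. It took 5 each way for the other day comparisons and for the difference of changes, and any member of a fixed list. The plan assumed that the comparisons of Non-NE with NE and of the days shared no library. That assumption was wrong, since NE replicate 2 is a part of day 0 replicate 1. Fits without NE replicate 2 were already among the planned fits that leave out each library, but their use for the shared reads was not planned. A test of gene sets chosen without it, the simulation of the shared reads and limma-voom with a quality weight per set were added after the data were seen. The alternatives were DESeq2 size factors, library totals only, no count filter, at least 1 CPM, the DESeq2 1.42.0 test, limma-voom, a 2-fold threshold, all 14 libraries in a fit, the replicate number as a block, and leaving out each library. A pseudocount alternative did not apply to counts.

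The pipeline was tested on simulated data with 200 changed genes per comparison. With the spread of the 6 NE and Non-NE libraries it recovered 2 of 100 genes changed 2-fold and 54 of 98 changed 4-fold, with 11 false calls among 12777 genes. With the spread of the YAP5SA libraries it recovered 86 of 95 and 96 of 99, with 7 false calls among 13595 genes.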

Results

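RNA was sequenced from cultured mouse small cell lung cancer cells in 14 libraries. The cells came from lung tumours that arise after Cre recombinase, driven from the calcitonin gene promoter of neuroendocrine cells, acts on floxed tumour suppressor genes. The labels name 3 neuroendocrine (NE) libraries, 3 non-neuroendocrine (Non-NE) libraries and 8 libraries of NE cells with an inducible YAP5SA, a form of the transcriptional coactivator YAP that the Hippo kinases cannot inactivate. The source and genotype text of day 0 replicate 1 lists no transgene, unlike that of the other 7. These 8 were taken 0, 3, 7 and 21 days into expression, with 2 libraries per day. The series asks how YAP bears on the division of these tumours into NE and Non-NE cells. The 14 libraries held 6730816 to 10659524 counts over genes. Values are CPM, counts scaled to library size, given as mean ± SD with n = 3 for NE and Non-NE and n = 2 for each day, and a group at 0 allows up to 3 counts over the group, 0.104 to 0.152 CPM depending on the group. NE replicate 2 held no more counts than day 0 replicate 1 in any of 32926 genes and differed from a random 85.7% of it by no more than sampling noise, so those libraries count as 1 read set, and NE and day 0 are not independent.

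Yap1, on chromosome 9 from 7931999 to 8004596 on the minus strand of mm10, was low in NE libraries at 19.2, 8.20 and 11.6 CPM. It stood at 134.5, 257 and 226 CPM in the Non-NE libraries, 15.4-fold higher in edgeR (log2 change 3.94, SE 0.42, adjusted p = 0.000549). At day 0 of the YAP5SA series the libraries held 7.87 and 7.13 CPM. The level rose to 1148 ± 120.1 CPM at day 3, 152-fold higher, and then fell to 763 ± 41.8 CPM at day 7 and 213 ± 8.02 CPM at day 21. The day 21 level was 28.8-fold above day 0. A single count per library holds transgene and endogenous transcripts together. Wwtr1, which encodes the YAP paralogue TAZ, had 0 counts in NE and day 0 libraries, 197 ± 22.5 CPM in Non-NE libraries and 9.22 ± 0.842 CPM at day 21. Of the floxed genes, Rb1 (chromosome 14, 73183673 to 73325822) was 10.4-fold lower in Non-NE than NE (5.72 ± 1.18 against 57.6 ± 18.8 CPM) and fell 2.73-fold from day 0 to day 21. Trp53 was at 15.8 ± 3.42 CPM in NE and 16.4 ± 3.01 CPM in Non-NE (edgeR log2 difference 0.01, SE 0.30, adjusted p = 0.986) and fell 2.06-fold by day 21. The counts do not show which exons the reads covered.

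**Figure D1:**
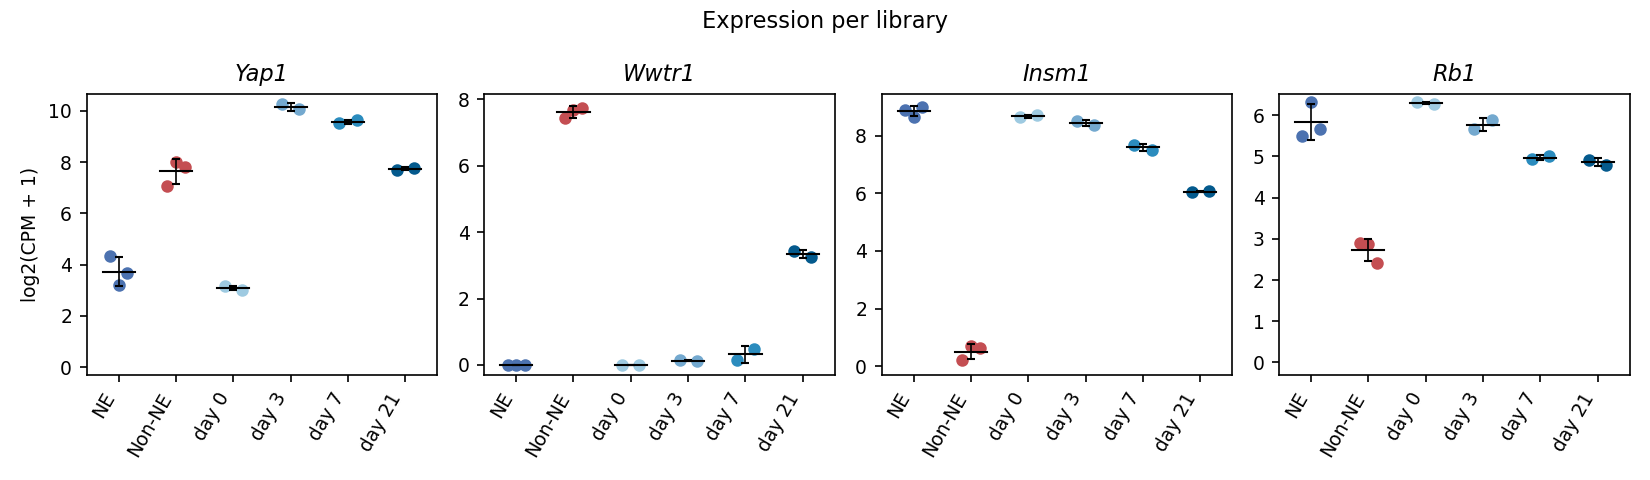
Yap1, Wwtr1, Insm1 and Rb1 in each library, as log2(CPM + 1) on the vertical axis, for NE and Non-NE (n = 3 each) and the 4 days of YAP5SA (n = 2 each), with points for libraries, bars for means and whiskers for SDs. Yap1 peaked at day 3 and at day 21 stood at 213 CPM, near the Non-NE mean of 206 CPM, while Insm1 stood at 65.7 CPM at day 21 and 0.436 CPM in Non-NE.

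Neuroendocrine and epithelial genes were mostly lower in Non-NE than in NE, although none of these lists passed camera with an estimated correlation. Insm1, a transcription factor of neuroendocrine cells, fell from 462 ± 54.0 CPM in NE to 0.436 ± 0.237 CPM in Non-NE (1006-fold), and the granule protein chromogranin A, Chga, fell 1506-fold. Of 20 tested genes of a neuroendocrine score list, 19 were lower in Non-NE and 0 higher (adjusted p = 0.0516 with an estimated correlation). Lower members made up 30 of 36 synaptic and neuronal genes, with 1 higher, and 15 of 17 secretory granule and hormone genes, with 1 higher (adjusted p = 0.0516 and 0.123 with an estimated correlation). The adhesion genes Cdh1 (1057 ± 267 against 4.92 ± 3.79 CPM) and Epcam (643 ± 182 against 0.117 ± 0.122 CPM) were among 20 lower members of 23 epithelial genes, with 0 higher (adjusted p = 0.0516 with an estimated correlation). Among 17 tested lineage transcription factors of the disease 10 were lower, including Nkx2-1, Foxa1, Prox1 and Mycl, and 3 higher, Yap1, Nfib and Sox9 (adjusted p = 0.398 with an estimated correlation). Glycolysis and hypoxia genes were lower in 15 of 26, among them Ldha, Gpi1 and Bnip3, with 0 higher (adjusted p = 0.459 with an estimated correlation). Among the genes with the steepest falls, each with 0 counts in every Non-NE library, were the secretogranin gene Scg3 (at least 1838-fold lower), the vesicle release gene Cadps2, the potassium channel genes Kcnip2, Kcnk1 and Kcnc1, and Mapk13, Mpp3, Dab1 and Serpinb12.

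Non-NE libraries expressed matrix and YAP target genes that were near 0 in NE. Vim, the intermediate filament of mesenchymal cells, stood at 6756 ± 2343 CPM against 0.601 ± 0.958, Fn1 at 10430.5 ± 5487 against 1.26 ± 0.899 and Col1a1 at 9968 ± 4427 against 1.68 ± 1.61. Higher members made up 19 of 20 mesenchymal genes with 0 lower, and 26 of 29 collagen and matrix genes with 1 lower, Col18a1 (adjusted p = 0.0516 and 0.0575 with an estimated correlation). All 8 tested fibroblast markers of 19 listed were higher, including Pdgfrb at 468 ± 354 CPM (adjusted p = 0.141 with an estimated correlation). A marker near 0 in NE was tested only if it was high in Non-NE. The filter thus fixed part of this direction, as for the mesenchymal, matrix and cytokine lists. Of the 19 markers 5 are also in the mesenchymal or matrix lists. YAP and TAZ targets were higher in 17 of 22 with 0 lower (adjusted p = 0.0773 with an estimated correlation). Ctgf had 0 counts in NE and 185.1 to 2803.5 CPM in the Non-NE libraries, so that a single library carried most of its mean of 1060.4 CPM, and DESeq2 gave no adjusted p for it. Ankrd1 was at least 2884-fold and Cyr61 1097-fold higher. Hippo pathway components were higher in 13 of 23 and lower in 2, focal adhesion genes higher in 27 of 30 and lower in 1, and TGF-beta pathway genes higher in 14 of 25 and lower in 2 (adjusted p = 0.0516, 0.123 and 0.269 with an estimated correlation). Cytokine and inflammatory genes were higher in 14 of 19 with 0 lower, including the chemokine Cxcl12 at 1357 ± 475 CPM and the prostaglandin synthase Ptgs2 at 289.6 ± 249.8 CPM (adjusted p = 0.0516 with an estimated correlation). Members of a non-neuroendocrine score list were higher in 15 of 20 and lower in 2 (adjusted p = 0.0516 with an estimated correlation). The remaining steep named rises, each from 0 NE counts, were Cav1 at 722 ± 272 CPM, Npr3, Wisp1, S100a11, F2r and Fndc1, whose call (adjusted p = 0.0386) was lost with no filter, with limma-voom and without NE replicate 1, 2 or 3 or Non-NE replicate 1. Few proliferation genes were called, with 2 of 26 G2/M genes higher and 3 lower. In edgeR 0 of 23 DNA repair and drug response genes passed the test, against 42.8% of all genes tested. With this spread simulated data gave 2 of 100 genes changed 2-fold, so smaller changes in these lists would be missed.

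The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 5554 of 12966 genes between Non-NE and NE (2594 higher, 2960 lower) at an adjusted p under 0.05. Scaling by library totals alone gave 1929 higher and 3756 lower, and a fit with all 14 libraries called 8997. Camera with its preset correlation called 16 of 34 lists, namely each list described above except proliferation and repair, plus ribosomal proteins (8 of 34 higher, 0 lower), and 0 held with an estimated correlation (12 at an unadjusted p under 0.05; fry called 23). For ribosomal proteins the adjusted p was 0.459 with an estimated correlation. Counts adjusted over the list alone were the same for these 16 lists except 28 higher and 2 lower for focal adhesion, 16 higher for the non-neuroendocrine score and 15 higher for TGF-beta and 4 higher for ribosomal proteins.

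**Figure D2:**
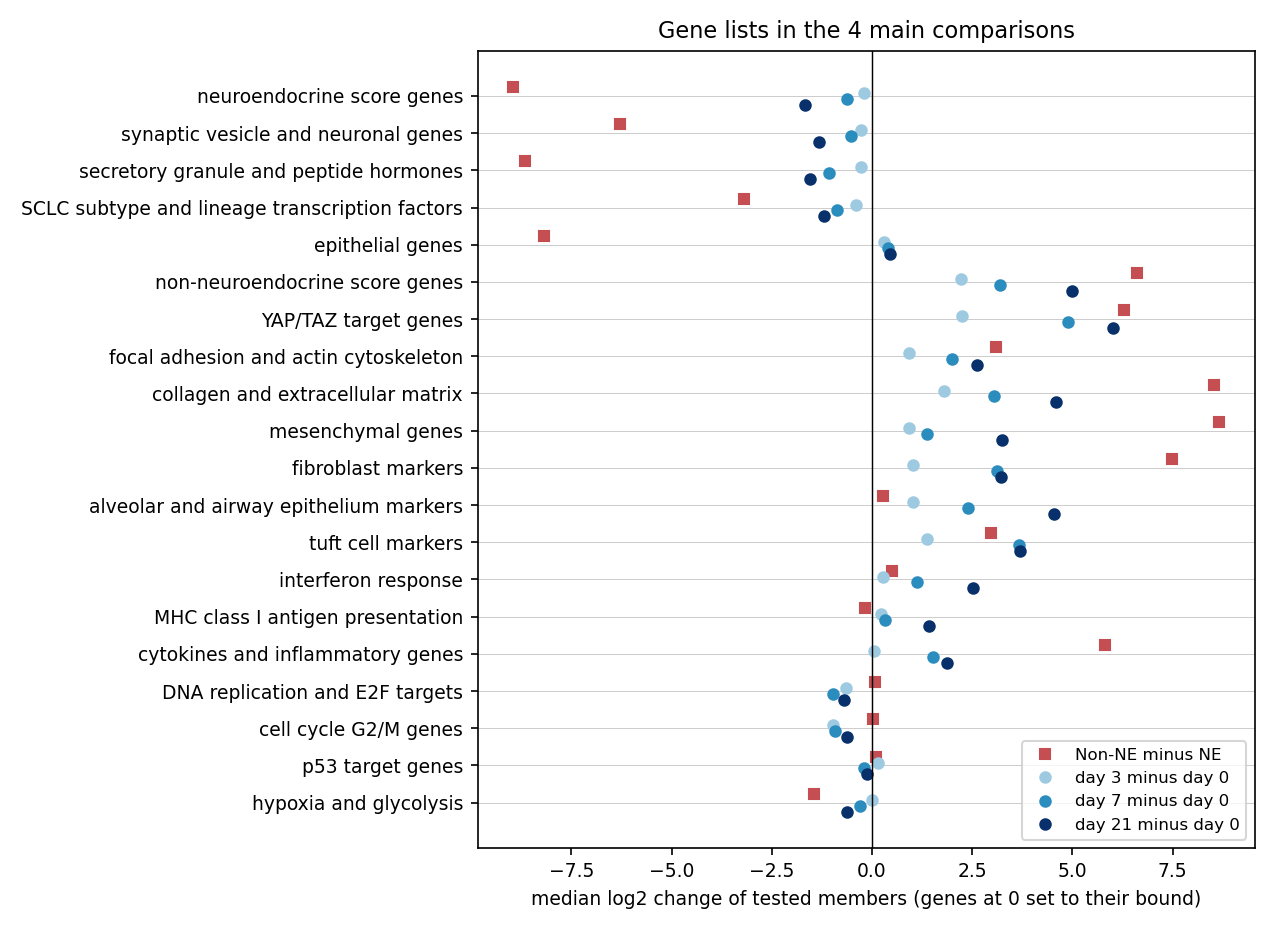
Median log2 change over the tested members of 20 gene lists (horizontal axis) for Non-NE minus NE (squares) and for days 3, 7 and 21 minus day 0 of YAP5SA (circles, light to dark), with genes at 0 in one group set to their bound. The epithelial list lies at -8.18 for Non-NE minus NE and at 0.46 for day 21 minus day 0, while the YAP/TAZ target list lies at 6.29 and 6.01.

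At day 3 most YAP target and Hippo pathway genes were above day 0 and nearly all proliferation genes below it, although none of these lists passed camera with an estimated correlation. No library without the transgene was labelled for days 3, 7 or 21, so its effect and that of time in culture were not told apart. Ager, a marker of the flat gas-exchange cells of the alveolus, rose from 4.84 ± 0.483 to 1013 ± 207 CPM, 207-fold. Alveolar and airway markers were higher in 7 of 15 and lower in 3 (adjusted p = 0.163 with an estimated correlation). The target Cyr61 rose 930.1-fold. Ajuba, an inhibitor of the Hippo kinases, rose 1435-fold. Tead4, Kifc3 and Stx11 rose from 0 to between 24.3 and 26.9 CPM. Higher members made up 12 of 20 YAP/TAZ targets with 3 lower (adjusted p = 0.115 with an estimated correlation) and 19 of 24 Hippo components with 0 lower (adjusted p = 0.120 with an estimated correlation). All 26 G2/M genes fell, Mki67 2.04-fold and Top2a 2.12-fold, as did 28 of 30 replication genes (adjusted p = 0.120 and 0.0817 with an estimated correlation). Of the neuroendocrine score list 4 genes rose and 11 fell, and the list did not pass camera from limma (adjusted p = 0.198 with the preset correlation). Among the steepest named falls were B3galt5 (6.26-fold), Ky, Islr2, Ccdc154 and Bcas1.

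Between days 3 and 7 YAP/TAZ targets rose in 17 of 20 and fell in 1, focal adhesion genes rose in 25 of 31 and fell in 2, and alveolar and airway markers rose in 8 of 15 and fell in 3. Their adjusted p were 0.106, 0.167 and 0.171 with an estimated correlation. Ager reached 4426 ± 307 CPM, and Pdpn, another type I marker, rose from 2.98 ± 0.0507 CPM at day 3 to 256 ± 10.1 at day 7. Clic5, Ankrd1, Wisp1 and Slco2a1 rose from 0 at day 0 to 560.5, 208, 169 and 136 CPM. All 31 tested focal adhesion and actin genes were above day 0 (adjusted p = 0.102 with an estimated correlation), as were 16 of 20 YAP/TAZ targets with 2 lower (adjusted p = 0.0706 with an estimated correlation). Secretory granule genes were lower in 18 of 20 (adjusted p = 0.0706 with an estimated correlation) and higher in 2. Steep falls against day 0 were seen for Dcpp2 (45.5-fold), Ccdc33, Ccdc154 and B3galt5. Between days 3 and 7 the water channel Aqp1 rose 675-fold and Serpinb9b 375-fold, with Col5a2, Scel and Cav1 also among the steepest rises. Cpne5, Th, Mcoln3 and Stac2 were among the genes that fell most over that interval, Th, the rate-limiting enzyme of catecholamine synthesis, by 6.96-fold.

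By day 21 YAP target, matrix and alveolar genes had mostly risen in YAP5SA cells and neuroendocrine genes mostly fallen, while epithelial genes went both ways, and none of these lists passed camera with an estimated correlation. Ctgf stood at 530.5 ± 1.66 CPM and Ankrd1 at 447 ± 7.75 CPM, both from 0 at day 0, and 19 of 20 YAP/TAZ targets were higher with 0 lower (adjusted p = 0.0638 with an estimated correlation). Sparc, a matrix glycoprotein, rose from 0.139 ± 0.196 to 1726 ± 100.5 CPM, and Fn1 from 0.140 ± 0.0671 to 70.7 ± 8.81 CPM. Matrix genes rose in 21 of 23 and fell in 2. Mesenchymal genes rose in 12 of 16 and fell in 1, with Vim at 21 ± 2.88 CPM (adjusted p = 0.0728 with an estimated correlation for both lists). Of 33 matrix, 24 mesenchymal and 22 alveolar and airway genes listed, 23, 16 and 15 had enough counts to be tested. Those near 0 at day 0 were tested only if they rose on some day, so the filter fixed part of these directions. Cdh1 was 1.44-fold higher than at day 0 and Epcam 1.86-fold lower, within an epithelial list of 14 higher and 4 lower of 24 (adjusted p = 0.446 with an estimated correlation). Alveolar and airway markers were higher in 13 of 15 and lower in 2, including Ager at 1913 ± 324, Pdpn at 699 ± 49.3, Aqp5 at 198 ± 25.9 and Hopx at 174 ± 15.9 CPM (adjusted p = 0.0638 with an estimated correlation). Neuroendocrine score genes fell in 17 of 21 and rose in 3 (adjusted p = 0.114 with an estimated correlation). Insm1 fell 6.10-fold and Chga 3.74-fold, whereas the axonal motor gene Kif1a rose 1.21-fold. Rest, a repressor of neuronal genes, rose from 0.0925 ± 0.131 to 32.2 ± 3.3 CPM and Notch2 7.0-fold. Other steep rises, each from 0 at day 0, included Clic5 to 878 CPM, Mal, Msln, Mpzl2, Serpinb6b, Col5a2 and Cav1. Other steep falls included Wif1 (78.0-fold), the neurofilament Nefl (48.7-fold), B3galt5, Hdac9, Cpne5, Gjd2, Dmpk and Ccno.

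Interferon response genes rose both before and after day 7. Of 25, 15 were above day 0 and 3 below at day 7, and 23 above and 1 below at day 21 (adjusted p = 0.168 and 0.0638 with an estimated correlation). A total of 15 rose and 2 fell between days 3 and 7, and 22 rose and 0 fell between days 7 and 21 (adjusted p = 0.167 and 0.173 with an estimated correlation). MHC class I presentation genes rose in 16 of 18 and fell in 1 over those last 14 days (adjusted p = 0.173 with an estimated correlation). B2m, the invariant MHC class I chain, went from 10.1 ± 0.0407 CPM at day 0 to 151 ± 0.430 at day 7 and 400.3 ± 89.2 at day 21. Cd274, which encodes PD-L1, rose 4.44-fold after day 7, to 118 ± 0.857 CPM. The steepest named rises from day 7 to day 21 were Pla2g4a, the hyaluronan receptor Cd44 (152-fold), Vim, Tnfsf18 and the club cell secretory gene Scgb1a1, which reached 19.8 ± 2.69 CPM. Cplx1 (21.1-fold), Slc39a4, Nkx2-6, Zfp493 and C3 fell most, after a peak at day 7. G2/M genes were below day 0 in 25 of 26, although 17 rose between days 7 and 21 (adjusted p = 0.144 and 0.298 with an estimated correlation).

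The same test called 6801, 9932 and 10032 of 13996 genes at days 3, 7 and 21 against day 0 (3673, 5208 and 5273 higher), of which 1942, 4371 and 4387 changed at least 2-fold. It called 7788 between days 3 and 7 and 7044 between days 7 and 21, and 11986 over the whole series. The biological coefficient of variation between the 2 libraries of a day was 0.0548 against 0.399 among NE and Non-NE libraries, and nothing says that the 2 came from separate cultures, so these p-values measure only that spread, which may be technical. Pearson correlations of log2(CPM + 1) were 0.9979 to 0.9987 within a day, against 0.974 to 0.985 between NE libraries. These values give no sign of more than 1 YAP5SA line, and the response of another line is not known. With the NE and Non-NE libraries in the same fit the counts were 1041, 4589 and 4586 against day 0, 1281 between days 3 and 7 and 515 between days 7 and 21. There B3galt5, Ky and Bcas1 at day 3, Col5a2, Th, Mcoln3 and Stac2 between days 3 and 7 and C3 between days 7 and 21 lost their calls. Without day 0 replicate 1, whose text lists no transgene, 5380, 8911 and 9112 genes were called at days 3, 7 and 21. Scaling by library totals alone turned 3673 higher and 3128 lower genes at day 3 into 3224 and 3705, 5208 and 4724 at day 7 into 4149 and 6115, 5273 and 4759 at day 21 into 4466 and 5761, and 4128 and 3660 between days 3 and 7 into 3140 and 5078. Of 34 lists camera called 15, 21 and 24 at days 3, 7 and 21, and 0 held with an estimated correlation (9, 9 and 15 at an unadjusted p under 0.05; fry called 26, 29 and 31). Adjusted over the list alone, the list counts given above for days 3, 7 and 21 were the same except 5 higher neuroendocrine score genes and 8 higher alveolar markers at day 3, and 20 higher YAP/TAZ targets and 13 higher mesenchymal genes at day 21. They were 17 higher interferon genes over days 3 to 7, and 23 higher interferon and 17 higher MHC class I genes over days 7 to 21.

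At day 0 the YAP5SA line was close to NE in the edgeR test, with 0 of 14829 genes called, 645 at an unadjusted p under 0.05, 36 by DESeq2 and 0 by limma-voom. Without NE replicate 2, which shares its reads with day 0 replicate 1, 928 were called. Day 21 libraries differed from Non-NE in 7859 genes (4405 higher at day 21, 3454 lower), or 5070 higher and 2682 lower by library totals alone. Both of these comparisons run between the NE and Non-NE libraries and the YAP5SA libraries, so library set and cell state cannot be told apart in them. Sets of genes were taken from the 6 NE and Non-NE libraries, so NE replicate 2 links them to day 0 through its shared reads. Of the 200 genes highest in Non-NE over NE, 48, 90 and 109 were called higher at days 3, 7 and 21. Only 111 of them had enough counts to be tested, and because they lay near 0 at day 0 that depended on their rise, so no test of this set is given. Of the 200 genes highest in NE, 128, 157 and 176 were lower at days 3, 7 and 21, and 26, 23 and 16 higher, with mean changes of -0.51, -1.42 and -1.53. Camera with an estimated correlation gave an adjusted p of 0.0102 at day 21 for an NE-high set chosen without NE replicate 2, a test added after the data were seen, and 0.00938 for the set from all 6 libraries. On a scale over all genes of both sets, with 0 at the NE mean and 1 at the Non-NE mean, the libraries stood at -0.0126 ± 0.000924 at day 0, 0.0704 ± 0.00824 at day 3, 0.234 ± 0.00135 at day 7 and 0.340 ± 0.00444 at day 21. At day 21 the genes gained stood at 0.444 ± 0.00791 and the genes lost at 0.230 ± 0.000730. Between days 7 and 21 the NE-high set had 51 genes higher and 86 lower (adjusted p = 0.251 with an estimated correlation, and 0.262 for the set chosen without NE replicate 2).

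**Figure D3:**
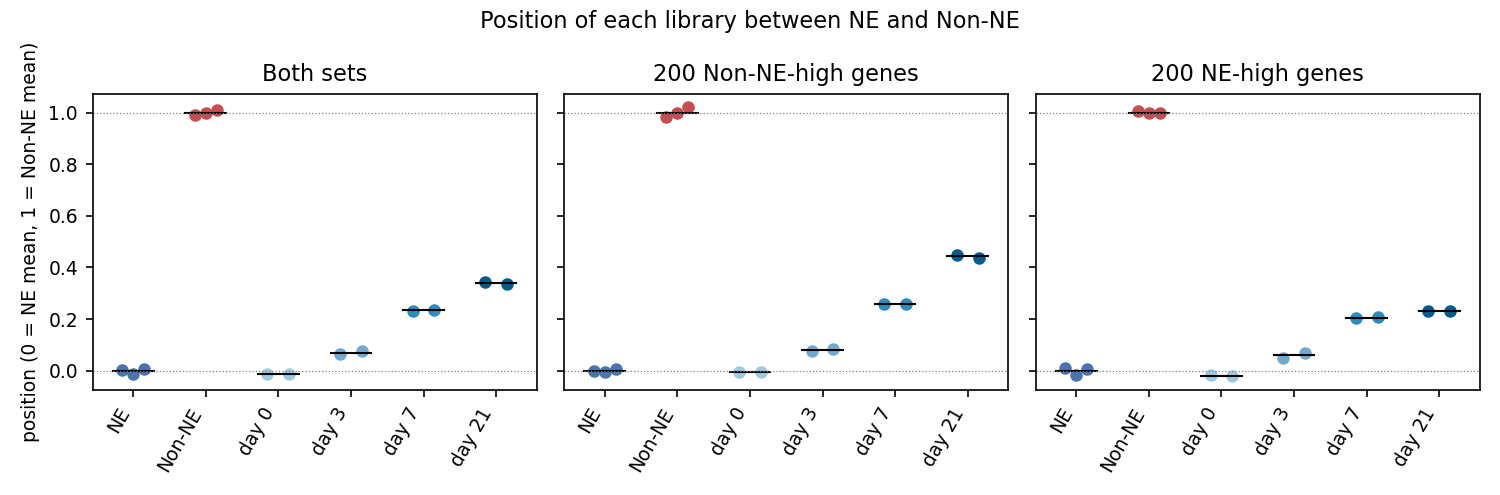
Position of each library between NE (0) and Non-NE (1) on the vertical axis, by group on the horizontal axis, from the mean log2(CPM + 1) of both sets of 200 genes (left), the Non-NE-high set (middle) and the NE-high set (right). Points are libraries and bars group means, and by day 21 the gained genes reached 0.444 and the lost genes 0.230.

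Across 12590 genes tested in both, the log2 change from day 0 to day 21 correlated with the Non-NE to NE difference at Pearson 0.631 and Spearman 0.549, a description across genes, which are not independent replicates. Without NE replicate 2, so that no reads were shared, the values were 0.618 and 0.530. Simulated libraries with that shared read set and no changed genes gave 0.0603 ± 0.0140 (SD over 20 simulations) and a covariance of 0.00558, against 0.632 and 2.46 for the same log2 CPM measure in the data. Both comparisons called 1669 genes up and 1957 down, where independent lists would share 823 and 1069. A further 465 genes were lower in Non-NE and higher at day 21, against 1054 for independent lists, and 194 the reverse, against 835. Independent lists are not a chance level here. A gene near 0 in both NE and day 0 can only rise, and expression level affects calling in both comparisons. The simulation and the fit without NE replicate 2 bear on the shared reads only.

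The test of the difference of changes asked which genes changed over the YAP5SA days otherwise than they differed between Non-NE and NE. The edgeR test called 4595 of 14829 genes, 3052 with the larger value under YAP5SA and 1543 with the smaller, or 3478 and 1033 by library totals alone. Of the 4595, 461 were called in both comparisons in opposite directions and 955 in the same direction, in the fit of all 14 libraries. A further 2461 were called only for Non-NE against NE, 596 only for day 21 against day 0 and 122 for neither. A larger value need not be a rise. Neuroendocrine score genes had median log2 changes of -1.68 at day 21 and -8.95 in Non-NE, with genes at 0 set to their bound. Epithelial genes led the test of the difference, with 23 of 24 called and 0 in the other direction, followed by 17 of 21 neuroendocrine score genes and 28 of 39 synaptic genes, each with 0 the other way. Their adjusted p were 0.00826, 0.00595 and 0.0184 with an estimated correlation, and adjusted over the list alone the called members were 23, 19 and 30. Replication genes differed downwards in 15 of 30 (17 adjusted over the list alone) and mesenchymal genes in 5 of 24, with 1 upwards, both at an adjusted p of 0.0217 with an estimated correlation. Over all genes tested 31.0% were called. All 24 listed mesenchymal genes were tested in this fit, against 16 in the fit of the days. Those near 0 in the other groups were tested only because they were high in Non-NE, so the filter fixed part of this direction. In this fit NE replicate 2 and day 0 replicate 1, which count as 1 read set, entered as separate libraries. These list tests were not run without NE replicate 2, where edgeR called 4864 genes. The fit also pooled the spread of the library sets. Its coefficient of variation was 0.293, against 0.399 among NE and Non-NE libraries and 0.0548 among day libraries, whose pairs may be technical. With a quality weight per set limma-voom called 5178 genes, and the list tests were not run that way. Col1a2, a fibrillar collagen chain, stood at 3781 ± 1424 CPM in Non-NE and 0.387 ± 0.412 CPM at day 21, and the galectin gene Lgals1 stood at 3900.3 ± 642 and 0.720 ± 0.0594 CPM. Adamts6, Fam20a and Tcf7l2 were the other genes named on that side. Clic5 (0.0551 CPM in Non-NE, 878 at day 21), Slc6a14, Atp6v0a4, Ceacam1 and a gene listed under the date 4-Sep had the largest differences the other way. YAP/TAZ targets had 2 members above and 1 below of 22 (adjusted p = 0.750 with an estimated correlation). Leaving out day 0 replicate 1 or 2 lowered the count to 2954 or 2829. Clic5 was not called without NE replicate 1, Tcf7l2 and Fam20a without day 0 replicate 2, or Col1a2 without day 0 replicate 1. Fam20a was also not called without NE replicate 3 or day 21 replicate 2.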

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

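The comparisons of read sets, the day 21 criterion for fibroblast genes and the tests of the Yap1 fall were chosen only after results were seen, and the Trp53, leukocyte and regrouping tests before.

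A test of the difference itself, the interaction contrast, picked every result in this paragraph, in edgeR for genes and in camera with an estimated correlation for lists. That camera test called 5 of 34 lists, and camera with its preset correlation called 17. The change from day 0 to day 21 differed from the Non-NE to NE difference in 4595 genes. The genes with the largest excess under YAP5SA were Clic5 (adjusted p = 0.00276), Slc6a14 (adjusted p = 3.09e-05), the gene listed as 4-Sep (adjusted p = 3.26e-06), Atp6v0a4 (adjusted p = 0.000841) and Ceacam1 (adjusted p = 3.78e-05). Those with the largest deficit were Adamts6 (adjusted p = 0.000368), Fam20a (adjusted p = 0.0325), Col1a2 (adjusted p = 0.000833), Tcf7l2 (adjusted p = 0.0211) and Lgals1 (adjusted p = 1.62e-06). By list, the median log2 difference of changes was 7.39 for neuroendocrine score genes, 8.66 for epithelial genes and 4.24 for synaptic genes, and it was -5.01 for mesenchymal genes and -0.87 for replication genes. For mesenchymal genes the count filter fixed part of the direction. A positive difference need not be a rise, since neuroendocrine score genes mostly fell in both comparisons. No group held 4 or more libraries, so none was tested for outlying libraries.

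NE replicate 2 and day 0 replicate 1 held nearly the same counts. Around a fixed share of 85.7%, the counts of NE replicate 2 had a chi-square per gene of 1.02, the value of random thinning of the same reads, and 0 of 32926 genes exceeded day 0 replicate 1. Libraries prepared or sequenced separately would give about 1 in a comparison of independent samples, and the value was 0.0788, against 1.71 for the pair of day 0 libraries. A single read set deposited under both titles, once in part, is therefore the likely origin. The counts cannot say which title is the right one.

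If the collagen and fibroblast genes of Non-NE libraries came from unrecombined stroma with intact Trp53, p53 targets should be higher, and of 18 tested 8 were higher and 5 lower with a median log2 change of 0.0875. The bounds written earlier against this origin, a median of 0.5 or less and Trp53 less than 1.5-fold higher, were both met, with Trp53 at a log2 difference of 0.01 (SE 0.30). The origin was left open only after these values were seen, because a median over targets that went both ways decides nothing and the effect of the deletion on the Trp53 count is unknown. Rb1, the other floxed gene, goes against intact stroma, at 4.35 to 6.45 CPM in Non-NE libraries and 44.0 to 79.1 CPM in NE, but the same holds for its count, and no bound had been set for it. A mixed culture with leukocytes and endothelium would show their markers, and 1 of 38 (Cd14) exceeded 10 CPM in every Non-NE library. If YAP5SA brought about the same state by day 21, the 8 fibroblast genes above 10 CPM in Non-NE should be there too, and 2 were above 10 CPM (Pdgfrb and Cd248) while 7 of 8 were lower than in Non-NE. Day 21 and Non-NE belong to different library sets, so set and state cannot be told apart in that comparison. The criterion of lower genes was added after the result was seen, and by the criterion written earlier, a bound at 0.25 of the genes, 2 of 8 left the question open. Fibroblasts that had lost the floxed genes are not excluded by these values.

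Yap1 counts fell between day 3 and day 21. Library scaling is unlikely to be the cause, since the Yap1 share of all counts fell 5.59-fold. If cells without the transgene had taken over, YAP/TAZ targets should have fallen as well, and their median log2 change from day 7 to day 21 was 1.00. Wwtr1, which encodes TAZ, rose from 0.102 and 0.407 CPM at day 7 to 9.81 and 8.62 CPM at day 21. Because endogenous TAZ or YAP could hold the targets up, their level cannot exclude such a loss of the transgene. A lower dose of the transgene within responding cells could not be tested, because a single count holds transgene and endogenous gene, which at day 21 stood 28.8-fold above day 0.

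Of the 10 ways to split the 6 NE and Non-NE libraries into 3 and 3, only 1, the real one, called as many as 5554 genes, and the highest other split called 0. With 10 splits the smallest possible share is 10%, so this cannot reach 0.05.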

How the results depend on the processing

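The weighted fits and the gene sets chosen without NE replicate 2 were picked only after results were seen. All other alternatives, with the fits that leave out each library, were picked before. Of results that answer a comparison, 390 values were the same and 32 moved. Of the others 3496 were the same, 52 stronger, 119 weaker and 1 reversed. The cause was not tested unless stated.

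A 2-fold threshold, which by construction removes genes, left 1942 genes at day 3, 4371 at day 7 and 4387 at day 21 against day 0, 2294 between days 3 and 7, 1782 between days 7 and 21 and 5553 over the series. With the other samples in the fit 8997 genes were called for Non-NE against NE in place of 5554, and for the days 1041, 4589, 4586, 1281 and 515 in the same order as above and 4610 over the series. That fit has a coefficient of variation of 0.293, between those of the sets. It called 9 gene lists at day 3 in place of 15, and fry called 26. With an estimated correlation 0 lists were called for Non-NE against NE, 0 at day 3, 0 at day 7 and 0 at day 21. The correlation across genes was 0.631, and it was 0.510 with no filter, 0.747 over genes called in both, 0.537 with other samples in the fit and 0.604 to 0.653 with a library left out. DESeq2 called 36 genes between day 0 and NE, and leaving out a library gave 0 to 928. The difference of changes had 4595 genes and 2829 to 5433 with a library left out. Where this left a single library in a group, it was assumed to vary like the others. The lineage transcription factor list at day 3 had a mean log2 change of -0.06, and -0.129 to 0.0159 with a library left out, reversed at 0.0159 without day 3 replicate 2. Yap1 is itself a member of this list and enters its mean. The 18 tested members had a median log2 change of -0.395, with 11 lower and 3 higher.

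With the replicate number as a replicate block 170 genes were called between day 0 and NE in place of 0, 4888 for Non-NE against NE, and 6707, 9873 and 9942 at days 3, 7 and 21, and the block moved no other count past 1.5 times. The labels do not say whether the numbers pair the libraries. Deviations of equal numbers in NE and Non-NE correlated at 0.0466, -0.0139 and 0.0412. No value was set for paired libraries, so these correlations cannot exclude pairing. For number 3 Xist differed, at 0.639 CPM in NE and 377 CPM in Non-NE, and so did the Y-linked Ddx3y, at 61.7 and 0.106 CPM. These values argue against a shared animal for the libraries of number 3. They do not bear on the other numbers or on pairing of another kind. Among the named genes Fndc1 lost its call with no filter (adjusted p = 0.0972), with limma-voom (0.0638) and without single libraries (0.0511 to 0.0765), and DESeq2 gave no adjusted p for Fndc1 and Ctgf. With the other samples in the fit B3galt5, Ky, Bcas1, Col5a2, Th, Mcoln3, Stac2 and C3 lost their call. The difference of changes was fitted on all 14 libraries, and on the libraries of its 4 groups alone Fam20a lost its call. Depth sets the floor of 0.104 to 0.152 CPM over a group below which a loss cannot be sized.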

Other observations

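No test of the next 2 paragraphs was chosen after results were seen, while the sex chromosome transcripts were looked up after the counts were seen.

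Receptor tyrosine kinases and their ligands rose widely under YAP5SA, and apoptosis, drug transport and Notch genes were divided. By day 21 kinase and ligand genes were higher in 23 of 27 and lower in 4 (adjusted p = 0.110 with an estimated correlation). Axl, a receptor often raised in drug tolerant cells, stood at 0.0931 ± 0.000843 CPM at day 0, 217 ± 1.55 at day 21 and 632 ± 139 in Non-NE, while Met stood at 161 ± 31.7 CPM in Non-NE and 0.816 ± 0.0583 at day 21. Kit, a receptor of neuroendocrine tumours, fell from 89.3 ± 0.114 to 14.2 ± 0.919 CPM and had 0 counts in Non-NE. Of the BCL2 family 7 rose and 8 fell of 15 by day 21, and the survival gene Bcl2l1 rose 2.70-fold, against a fall of 2.16-fold in Non-NE. Drug efflux and detoxification genes rose in 15 of 27 and fell in 10, with the transporter Abcc5 3.95-fold higher. Notch pathway genes rose in 6 of 15 and fell in 6. The last 3 lists did not pass camera (adjusted p = 0.991, 0.508 and 0.991). Adjusted over the list alone the counts were the same except 8 lower Notch genes.

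Tuft cell, fibroblast and cytokine lists had more members higher than lower at day 21, and none passed camera with an estimated correlation. Tuft cell markers were higher in 8 of 10 with 0 lower and fibroblast markers in 8 of 9 with 1 lower (adjusted p = 0.110 with an estimated correlation for both). Only 10 of 14 tuft cell, 9 of 19 fibroblast and 16 of 31 cytokine genes listed had enough counts to be tested. Those near 0 at day 0 were tested only if they rose on some day, so the filter fixed part of these directions. Cytokine and inflammatory genes rose in 13 of 16 and fell in 1 (adjusted p = 0.0728 with an estimated correlation), and the macrophage growth factor Csf1 rose 92.6-fold, to 137 ± 2.57 CPM, with 908 ± 229 CPM in Non-NE. Leukocyte markers rose in 3 and fell in 3 of 7, and endothelial markers likewise, and neither list passed camera. Hypoxia and glycolysis genes fell in 18 of 28 and rose in 7 (adjusted p = 0.446 with an estimated correlation). DNA repair and drug response genes fell in 12 of 23 and rose in 3, or 11 and 3 adjusted over the list alone (adjusted p = 0.151 with an estimated correlation). Unfolded protein response genes rose in 16 of 20 and fell in 2 between days 7 and 21 (adjusted p = 0.186 with an estimated correlation). The other counts of this paragraph were the same adjusted over the list alone.

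In NE replicate 3 Xist, expressed from the inactive X chromosome, was at 0.639 CPM and the Y-linked genes Ddx3y and Eif2s3y at 61.7 and 94.7 CPM. In the other 13 libraries Xist was at 377 to 1933 CPM and those Y-linked genes at no more than 0.106 CPM.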
